A study of Capra hircus with 8 samples.

How the data were processed

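Small RNA was sequenced from goat mammary gland cells grown in 3D culture, in 8 libraries that the labels place in 4 groups of 2: a control named 3NC, a control named 5NC, cells given the circular RNA circRNA28250 by virus (overexpression) and cells in which it was inhibited (knockdown). The series text lists 5NC next to overexpression and 3NC next to knockdown, and each control was paired with its neighbour on that basis, because the labels do not state the pairing outright. Nothing in the labels says whether the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

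The deposited table gives, per the file headers, a read count and a TPM value for each feature in each library. The counts were raw whole numbers as deposited, and the TPM values the authors deposited equalled the count divided by the column total and scaled to a sum of 1000000, with no length term, within 0.0141% for features of at least 1000 reads. A count of 0 was written as 0.001 in the TPM columns, and 1 feature had a TPM value shifted into a neighbouring column. The tests used the deposited counts, and the TPM columns were used only for this check. The aligner, the counting tool and the genome build are not given in the sources used here, so no genome positions are printed. How reads with several matching features were counted is not given either, so members of close families (let-7, miR-199, miR-92, miR-30) are uncertain one by one.

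The 5093 features of the table comprised goat miRNA names, predicted miRNAs, predicted piRNAs, Rfam families and 4 summed classes without a feature name (exon, intron, intergenic and repeat). These 4 classes held 44.3% to 63.1% of the reads of a library and stayed out of library sizes and tests. Goat miRNA names appeared as 317 mature and 347 hairpin features, 303 names had both with different counts, and the counts were summed per name. Whether a mature read is also counted in its hairpin feature is not given, and if so the sum counts it more than once, which changes CPM and raises miRNA shares. Mature features held 63.1% to 72.9% of the known miRNA reads of a library. This left 361 known and 664 predicted miRNAs. Known miRNAs carry the prefix chi- in the deposited table, which is left out here, and predicted ones are named as the table names them.

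Library totals ran from 6588354 to 32066029 reads and miRNA reads from 122435 to 5039336. The widest exact 95% binomial interval of a class share had a half-width of 0.0365 percentage points. Intervals and floors cover counting error only, because reads without molecular identifiers are not independent molecules. Levels are given as CPM, counts scaled to 1000000 miRNA reads after TMM factors, as mean ± SD of 2 libraries. A fold against a group at 0 in both libraries was computed against the mean of the floors of those libraries, 3 reads each, and is a lower bound.

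Counts were tested in R 4.3.3 with edgeR 4.0.16, using TMM factors (0.639 to 2.62), filterByExpr with a minimum count of 10, and the robust quasi-likelihood test on all 8 libraries with 4 residual degrees of freedom. The filter kept 402 miRNAs, 269 known and 133 predicted. P-values were two-sided and adjusted by Benjamini-Hochberg over the 402 miRNAs, with a threshold of 0.05. The SE of a log2 fold change was derived as its absolute value divided by the square root of the F statistic. It is approximate, above all where a group has few reads. The common dispersion was 1.43, a biological coefficient of variation of 1.19. An exact permutation test of 2 against 2 libraries cannot go below a p of 0.333, so none was used. DESeq2 1.42.0 was run as an alternative, and its missing adjusted p-values were left missing.

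Before the data were examined, 16 miRNA lists were fixed, covering the let-7 family, the miR-200 family, other epithelial miRNAs, mesenchymal, muscle, endothelial, blood, and liver and neural miRNAs, the miR-17/92 clusters, the DLK1-DIO3 cluster, the miR-34 and miR-449 family, the miR-29 and miR-30 families, inflammation-responsive miRNAs, miR-221 and miR-222 with hypoxia, and miRNAs linked to lactation and milk fat. The 15 lists with at least 3 measured members were tested with camera in limma 3.58.1 at its preset correlation of 0.01, adjusted over the lists of a comparison, with camera at an estimated correlation and fry beside it. Fry tests whether the members move one way on balance, without comparing them with other miRNAs. List medians did not move when members with a group at 0 were placed at their bound.

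The rule for named miRNAs was fixed at the same time. It took up to 8 per direction past the test with at least 10 CPM and no overlap between groups, and, where fewer than 3 qualified, the 5 with the lowest p, named as not past the test. It also took the 5 most abundant miRNAs, up to 4 members per list by level, and for the controls and the difference of effects the 3 with the lowest p per direction.

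The code was tested on simulated counts for the 402 miRNAs. At the dispersion estimated from these libraries, the overexpression comparison recovered 0%, 14.9% and 40.9% of miRNAs changed 4-, 16- and 64-fold and called 0.990% of unchanged ones. The knockdown comparison recovered 0%, 2.99% and 15.2% and called 0%. At a dispersion of 0.05 the recovered shares were 100%, 98.5% and 100% for overexpression and 73.1%, 89.6% and 87.9% for knockdown, with 3.96% and 4.46% of unchanged miRNAs called. A miR-30 list raised 8-fold was found in both comparisons, with 0 other lists called. The simulated miRNAs were drawn independently of each other, so this cannot show how often lists of correlated members are called wrongly.

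Alternatives covered scaling, filters, the tool, the libraries and controls in the fit, a replicate block, known miRNAs alone, mature and hairpin features apart, and leaving out each library. Scaling to miRNA totals, mature features alone, thinning each library to 122435 miRNA reads, leaving out the first 5NC and second overexpression libraries together, list tests with libraries left out, and miRNA shares with predicted piRNAs out of the totals were added after the data were examined. Fits with a library left out kept the 402 miRNAs, a choice made after the default filter was seen to test a different number there. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.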

Results

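Small RNA counts were analysed for 8 libraries of goat mammary gland cells in 3D culture, 2 per group, to compare miRNA levels after overexpression and after knockdown of circRNA28250. Circular RNAs are closed transcripts, and some are studied as binding partners of miRNAs. Library totals were 8084584 and 13080581 reads for 3NC, 15729279 and 12413546 for 5NC, 12459225 and 6889730 for overexpression, and 6588354 and 32066029 for knockdown. The level of circRNA28250 itself was not analysed here, since small RNA counts do not measure it, so the labels of the overexpression and knockdown libraries could not be checked against it.

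Known and predicted miRNAs took 21.5% and 20.3% of reads in the 3NC libraries and 32.04% and 23.8% in the 5NC libraries. The share was 39.51% (exact 95% binomial interval 39.48% to 39.53%) in the first overexpression library and 5.80% (5.79% to 5.82%) in the second. In the knockdown libraries it was 2.69% (2.68% to 2.71%) and 0.382% (0.380% to 0.384%), so that 177449 and 122435 miRNA reads remained there against 1734531 and 2649160 in 3NC. Ribosomal RNA made up 27.3% of the first knockdown library, against at most 4.89% in a control, and predicted piRNAs 43.9% of the second, against at most 0.303%. Whether these reads are also counted in the repeat class is not given. With predicted piRNAs left out of its total the miRNA share of the second knockdown library was 0.681%. This lies outside the interval above, which covers counting error alone. The repeat class stayed in that total, so the share would be higher still if it holds the same reads. By the mean of all 8 libraries the most abundant miRNAs were let-7b-5p (mean 146870 CPM), miR-222-3p (106843 CPM), miR-21-5p (82943 CPM) and the predicted novel_mir1 (81132 CPM) and novel_mir432 (75117 CPM). This order did not hold in each library, such as the first knockdown library, with 110025 CPM of miR-21-5p, 17701 CPM of let-7b-5p and 7028 CPM of miR-222-3p.

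**Figure D1:**
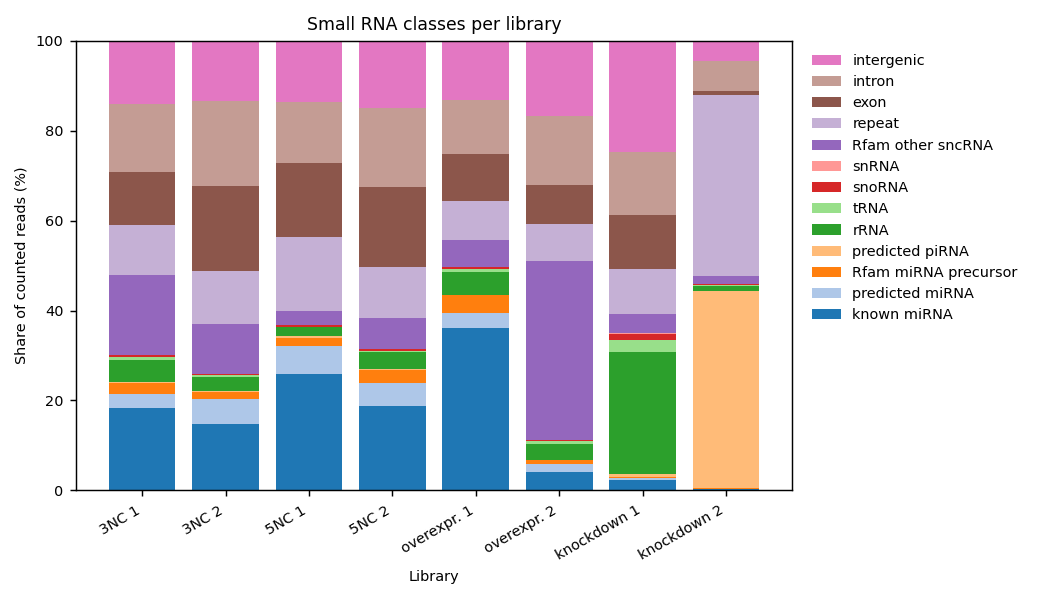
Share of counted reads (%) taken by each small RNA class in each of the 8 libraries, as stacked bars summing to 100%. Known and predicted miRNAs together took 20.3% to 39.5% in the controls and the first overexpression library, and 0.382% to 5.80% in the other 3 libraries.

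Libraries of a group differed widely. Across the 402 miRNAs tested, which are not independent replicates, the Spearman correlation within a group was 0.88 for 3NC, 0.63 for 5NC, 0.78 for overexpression and 0.76 for knockdown. The first 5NC library correlated at 0.52 to 0.63 with each of the other 7 libraries, whereas the second correlated at 0.87 and 0.84 with the 3NC libraries. In the first 5NC library miR-204-5p, a miRNA known from epithelia of the eye, stood at 17.3 CPM against 192258 CPM in the second and 65876 and 59785 CPM in 3NC. This miRNA was singled out after its values were seen.

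Overexpression against 5NC asked which miRNAs differ when more circRNA28250 is supplied. Among the miRNAs with the lowest p, miR-767 stood at 335.0 ± 122.3 CPM with overexpression and 1.70 ± 1.68 CPM in 5NC (log2 fold change 7.60 ± 1.81 SE, n = 2 per group, edgeR adjusted p = 0.49). Endothelial miR-126-3p had 3410 ± 4252 against 230 ± 32.6 CPM (log2 fold change 3.89 ± 1.31), with 403 CPM in one overexpression library and 6417 CPM in the other. MiR-192-5p, a miRNA abundant in gut, liver and kidney, had 469 ± 48.6 against 60.9 ± 7.76 CPM (2.94 ± 1.06). MiR-708-5p had 33.3 ± 22.7 against 0.627 ± 0.207 CPM (5.56 ± 1.98), and novel_mir261 had 27.6 ± 2.37 CPM against 0 reads in 5NC, at least 24.9-fold higher. The 5NC mean of miR-708-5p lay under the floors of those libraries (0.774 and 1.44 CPM) and that of miR-767 near them, so both fold changes are uncertain in size. On the lower side, miR-183 and miR-182, which are made from one cluster with miR-96, had 42.1 ± 10.7 against 5803 ± 7160 CPM (−7.10 ± 1.64) and 39.3 ± 0.629 against 1692 ± 2103 CPM (−5.42 ± 1.58).

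Predicted miRNAs completed the lower side. Novel_mir5 had 56.1 ± 18.5 against 4502 ± 5689 CPM (log2 fold change −6.33 ± 1.74), while novel_mir160 and novel_mir9 had 0 reads with overexpression against 328.7 ± 362.1 and 773 ± 1065 CPM, at least 88.4- and 207.8-fold lower. None of the 402 miRNAs passed the edgeR test, with a smallest adjusted p of 0.49, while 33 had an unadjusted p under 0.05 (10 higher, 23 lower) where chance gives 20.1. DESeq2 called 26 miRNAs (10 higher, 16 lower), among them all 10 named here. The groups did not overlap for 125 miRNAs (31.1%), where chance gives 33.3%. The first 5NC library carried most of the 5NC level of miR-183 (10866 against 740 CPM), miR-182 (3179 CPM, where the mean of both was 1692 CPM), novel_mir5 (8525 against 479 CPM), novel_mir9 (1526 against 19.7 CPM) and novel_mir160 (585 against 72.7 CPM), so their folds and bounds rest largely on it. EdgeR called 30 miRNAs without the second 5NC library and 0 without the first. Set against 3NC in place of 5NC, the overexpression group had 0 called miRNAs and 1 with an unadjusted p under 0.05.

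**Figure D2:**
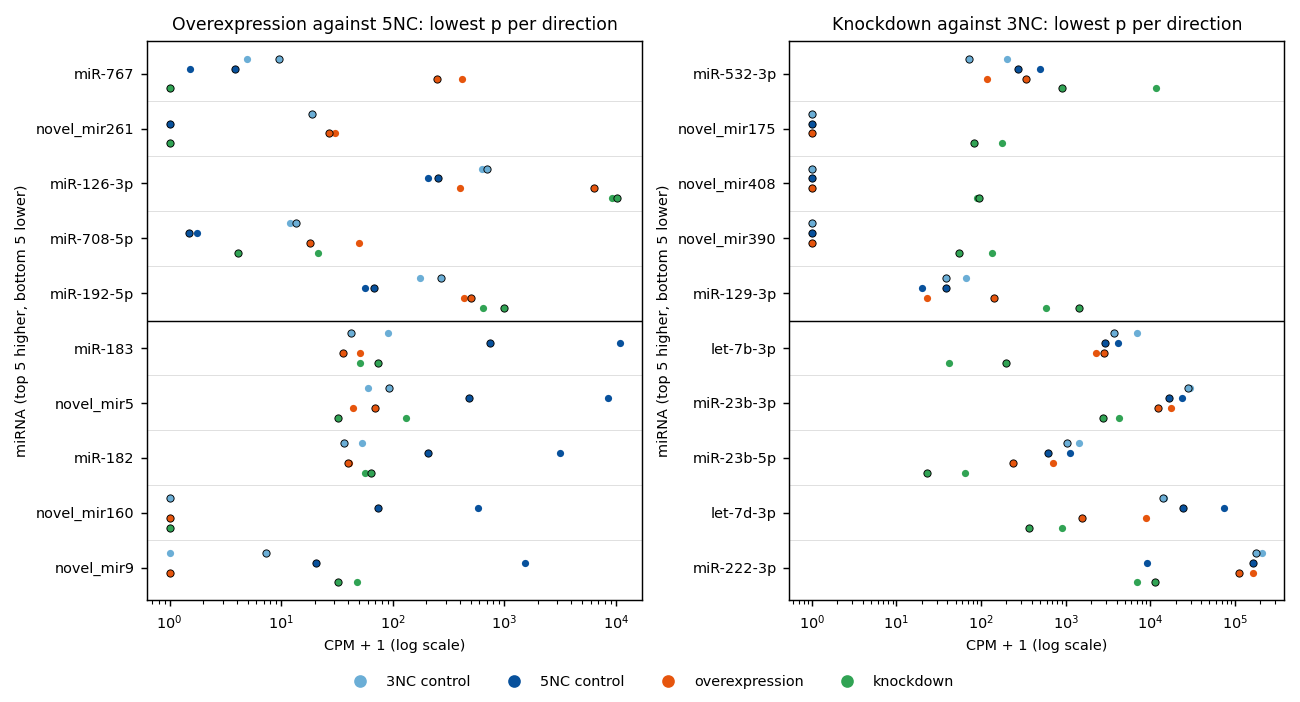
Level (CPM + 1, log scale) of the 5 miRNAs with the lowest p per direction in each main comparison, 1 point per library, coloured by group, with black edges on the libraries numbered 2. MiR-183 lay at 10866 and 740 CPM in 5NC and at 34.6 to 90.2 CPM in the other 6 libraries, and miR-222-3p at 7028 and 11358 CPM with knockdown.

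Of the miRNA lists in this comparison, the other epithelial list fell, with 3 of 3 measured members lower (miR-183, miR-182 and miR-96, median log2 fold change −5.42, camera adjusted p = 0.0109, but 0.56 with an estimated correlation), 2 of them past the test adjusted over the list alone and 0 over all miRNAs. These 3 are made from one cluster, so they are not independent, and no other member of the list was found in the deposited table. The mesenchymal list rose, with 8 of 8 members higher (median 1.85, adjusted p = 0.0387, but 0.73 with an estimated correlation) and 0 past either adjustment. Its miR-143-3p had 10744 ± 8473 against 2088 ± 2513 CPM and miR-145-5p, like it abundant in smooth muscle and fibroblasts, 1849 ± 2196 against 249.7 ± 329.4 CPM. The miR-17/92 clusters, which are tied to proliferation, fell with 14 of 17 members lower (median −1.48, adjusted p = 0.0109, but 0.56 with an estimated correlation), 0 past either adjustment. The shared entry of miR-92a-3p and miR-92b had 23808 ± 3760 against 66895 ± 5638 CPM, and miR-93-5p 1508 ± 30.4 against 4907 ± 1655 CPM. Fry called 0 lists. For all 3 lists 5NC stood apart from 3NC as well as from overexpression. The summed other epithelial miRNAs had a mean of 93.7 CPM with overexpression, 125.7 CPM in 3NC and 7612 CPM in 5NC. In the same order the mesenchymal sums were 23183, 29467 and 4452 CPM, and the miR-17/92 sums 25786, 32337 and 75183 CPM. These calls therefore depend on 5NC as the control.

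The other epithelial and mesenchymal lists also parted the 5NC libraries. The summed other epithelial miRNAs reached 14246 CPM in the first against 978 CPM in the second, and the mesenchymal ones 516 against 8389 CPM. Without the first 5NC and the second overexpression library the adjusted p-values of the other epithelial, mesenchymal and miR-17/92 lists were 0.084, 0.36 and 0.29, and without the second overexpression library alone 0.069, 0.069 and 0.13. The mesenchymal call was also lost without the first 5NC (0.37) or the first overexpression library (0.13), and without either 3NC library (0.055 and 0.056), which enter through the shared spread, with totals of all named small RNAs (0.072) and after thinning to equal depth (0.11).

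None of the remaining lists was called by camera in the main fit of this comparison. With the replicate number as a block, camera called the muscle list (adjusted p = 0.027). All 5 miR-200 members (median 2.66, adjusted p = 0.24), 5 of 5 muscle (2.85, 0.24), 4 of 4 blood (2.65, 0.099), 5 of 6 liver and neural (0.88, 0.37), 5 of 6 miR-29 (1.35, 0.24) and 3 of 3 miR-221 and miR-222 members (0.65, 0.41) lay higher. Lower were 10 of 17 let-7 members (−0.44, 0.099) and 10 of 11 miR-30 members (−0.999, 0.055). With totals of all named small RNAs the miR-200, muscle and blood medians shrank to 0.68, 1.05 and 0.95, with 4, 3 and 3 members higher. The miR-30 median was then −2.64. Members of the miR-34 and miR-449 family (1.007, 0.25), the DLK1-DIO3 cluster (0.48, 0.86) and the lactation and milk fat list (−0.15, 0.58) went both ways, and the sign of their medians turned under another scaling (−0.67, −0.68 and 0.11). The inflammation-responsive list had a median of 0.98, a mean of −1.05 and a camera direction of down (adjusted p = 0.74). The endothelial list held only miR-126-3p and miR-126-5p, both higher (median 3.04), 1 of them past the test adjusted over the list alone. Across these lists the members past the test over all miRNAs numbered 0. Some of these directions rested on the second overexpression library: the summed miR-200 members had 52.8 CPM in the first and 553 CPM in the second, against 60.6 and 72.7 CPM in 5NC. Summed muscle miRNAs had 229 and 3724 CPM with overexpression against 171 and 1355 CPM in 5NC, so both groups were higher in the second library. Without the first overexpression library the let-7 (adjusted p = 0.00048), miR-200 (0.0011) and blood lists (0.0082) were called, and without the second the miR-200 and muscle lists pointed down and let-7 up. Blood was also called without the first 5NC library (0.048), let-7 without the second (0.037) and miR-30 without either knockdown library (0.041 and 0.0399).

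Knockdown against 3NC asked which miRNAs differ when circRNA28250 is inhibited. MiR-222-3p, which targets the cell cycle inhibitor CDKN1B, had 9193 ± 3062 CPM with knockdown and 193885 ± 21486 CPM in 3NC (log2 fold change −4.40 ± 1.31 SE, n = 2 per group, edgeR adjusted p = 0.43). The miR-221 and miR-222 members of the first 5NC library summed to 9851 CPM, so a low level also occurred in a control. The passenger strands let-7b-3p and let-7d-3p had 119 ± 111 against 5339 ± 2315 CPM (−5.48 ± 1.18) and 632 ± 370 against 14266 ± 402 CPM (−4.50 ± 1.20). Both arms of miR-23b were lower, the 3p arm at 3532 ± 1070 against 28842 ± 994 CPM (−3.03 ± 0.77) and the 5p arm at 43.1 ± 29.9 against 1239 ± 289 CPM (−4.84 ± 1.29). Higher were miR-532-3p, with 6253 ± 7572 against 135.2 ± 91.6 CPM (5.53 ± 1.59), and the neural miRNA miR-129-3p, with 1022 ± 607 against 51.7 ± 20.1 CPM (4.30 ± 1.42).

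The predicted novel_mir175, novel_mir408 and novel_mir390 had 128.5 ± 66.1, 91.0 ± 4.71 and 93.9 ± 57.2 CPM with knockdown and 0 reads in 3NC, at least 62.9-, 44.5- and 46.0-fold higher. None of the 402 miRNAs passed the edgeR test, with a smallest adjusted p of 0.43, while 44 had an unadjusted p under 0.05 (18 higher, 26 lower) where chance gives 20.1. DESeq2 called 25 (16 higher, 9 lower, 94 without an adjusted p), among them all 10 named here. The groups did not overlap for 210 miRNAs (52.2%), where chance gives 33.3% and the 2 control groups gave 189 (47.0%). The scaling set the centre of this comparison: the median log2 fold change of all miRNAs was −0.13 with TMM, 0.00 with DESeq2 size factors, 1.43 with miRNA totals and −2.27 with totals of all named small RNAs. The same medians for overexpression were 0.19, 0.42, 0.35 and −0.51, and fold changes here are relative to the TMM centre.

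Among the lists with knockdown, the miR-200 family, which marks epithelial cells, rose with 5 of 5 members higher (median 3.35, and 1.11 to 5.04 under the other scalings, camera adjusted p = 0.032, but 0.69 with an estimated correlation), and 0 members passed the test adjusted over the list alone. Its miR-429 had 592 ± 402 against 52.97 ± 7.17 CPM and miR-200b 188 ± 1.15 against 18.3 ± 12.9 CPM. Blood miRNAs rose with 4 of 4 members higher (median 3.23, and 1.21 to 4.92, adjusted p = 0.036, but 0.56 with an estimated correlation) and 0 past the test over the list alone, with lymphocyte miR-150 at 1515 ± 493.2 against 83.2 ± 28.7 CPM and myeloid miR-223-3p at 308 ± 324 against 22.1 ± 7.58 CPM. The list of miR-221, miR-222 and hypoxia, the miR-221 list for short, fell with 3 of 3 members lower (median −3.75, and −5.78 to −2.06, adjusted p = 0.0497, but 0.69 with an estimated correlation), 1 of them past the test adjusted over the list alone. Its hypoxia member, miR-210, was not in the deposited table, and miR-221-3p and miR-221-5p are arms of one hairpin. The list summed to 7834 and 12367 CPM with knockdown, but also to 9851 CPM in the first 5NC library, against 165402 CPM in the second.

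Calls on 3 further lists had medians whose sign depended on the scaling. The let-7 family fell with 12 of 17 members lower (median −1.04 but 0.59 with miRNA totals, adjusted p = 0.036, and 0.73 with an estimated correlation), 1 past the test adjusted over the list alone. Its let-7b-5p had 19272 ± 2222 against 220304 ± 13164 CPM and let-7a-5p 11417 ± 1242 against 87136 ± 1131 CPM. The miR-30 family rose with 8 of 11 members higher (median 1.80 but −0.38 with totals of all named small RNAs, adjusted p = 0.036, and 0.56 with an estimated correlation), with miR-30c-5p at 627 ± 131 against 51.6 ± 0.286 CPM. Summed miR-30 members had 3952 and 3278 CPM with knockdown, 3370 and 2244 CPM in 3NC, and 8060 and 8104 CPM in 5NC. The direction of this sum thus depends on 3NC as the control. The imprinted DLK1-DIO3 cluster rose with 15 of 18 members higher (median 1.74 but −1.21 with those totals, adjusted p = 0.045, and 0.69 with an estimated correlation), with miR-127-3p at 819 ± 802 against 149.0 ± 135.3 CPM. None of the 6 knockdown calls thus held with an estimated correlation, and fry called 0 lists.

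Apart from the let-7 and miR-221 members counted, 0 miRNAs of these 6 lists passed the test adjusted over the list alone, and 0 passed it over all miRNAs. All 6 calls were lost without the second knockdown library (adjusted p = 0.059 to 0.48) and without the second 3NC library (0.070 to 0.17). All 6 were also lost with totals of all named small RNAs (0.051 to 0.24), and without the first 3NC library only the let-7, miR-200 and DLK1-DIO3 calls held. After thinning to equal depth only the let-7 call held (0.021), those of the miR-200 (0.093), miR-30 (0.093), blood (0.103) and miR-221 lists (0.103) were lost, and the DLK1-DIO3 list was not tested there. The miR-30 and miR-221 calls were lost without the first knockdown library (0.12 and 0.14), the let-7 call without the first or the second 5NC library (0.067 and 0.066) and the miR-221 call without either overexpression library (0.080 and 0.082).

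Endothelial miR-126-3p had 9697 ± 731 CPM with knockdown against 667.7 ± 44.8 CPM in 3NC and miR-126-5p 171 ± 73.1 against 9.11 ± 1.80 CPM, both past the test adjusted over their list of 2 alone and neither over all miRNAs. The second overexpression library, also with few miRNA reads, had 7828 CPM of summed blood miRNAs against 5567 and 5692 CPM with knockdown and at most 2963 CPM in a control. Its summed miR-200 members reached 553 CPM against 1203 and 663 CPM with knockdown and at most 141.2 CPM in a control. Its summed let-7 members had 66860 CPM, against 66267 and 48196 CPM with knockdown and at least 267242 CPM in a control. A low let-7 level thus also occurred without the knockdown label. The miR-221 list did not follow this, at 114863 CPM there against 7834 and 12367 CPM with knockdown. Summed muscle (418 CPM) and liver and neural miRNAs (1455 CPM) of the first knockdown library lay within the range of the controls.

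**Figure D3:**
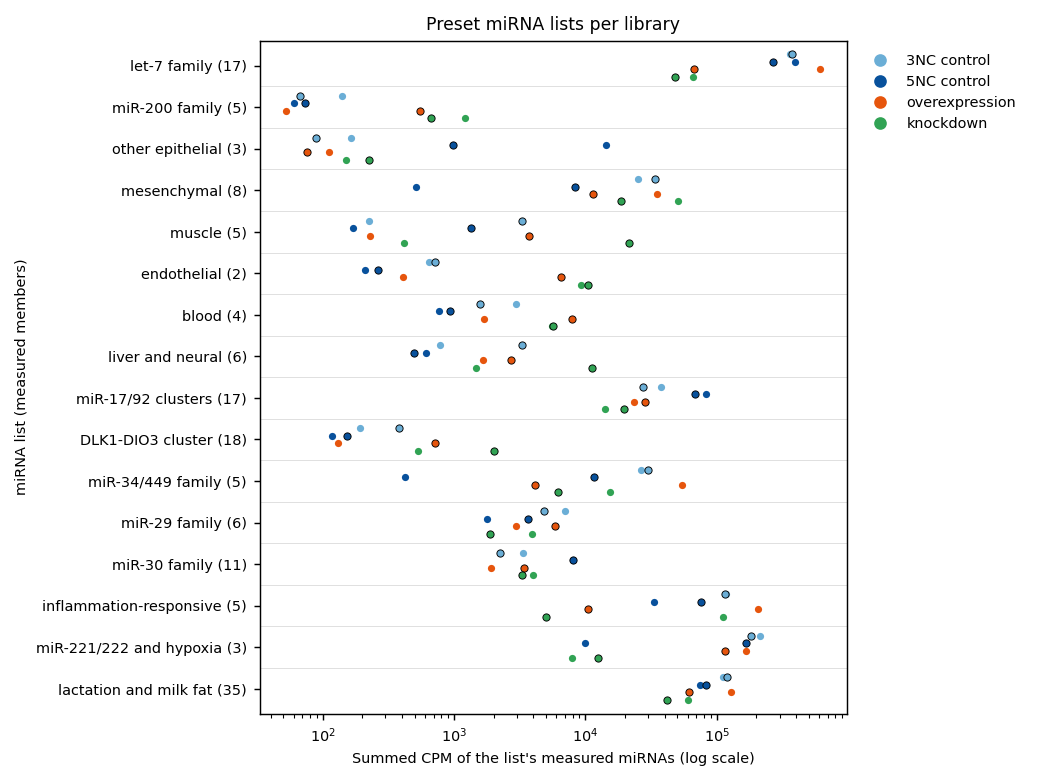
Summed CPM (log scale) of the measured miRNAs of each preset list, 1 point per library, coloured by group, with black edges on the libraries numbered 2 and the number of measured members in brackets. The endothelial list stood at 6469 to 10437 CPM in both knockdown libraries and the second overexpression library, and at 210 to 710 CPM in the other 5.

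None of the remaining lists was called by camera in the main fit with knockdown, and 0 of their members passed either adjustment, endothelial ones apart. With the replicate number as a block, camera called the muscle list (adjusted p = 0.031). All 5 muscle members (median 2.44, adjusted p = 0.27), 4 of 6 liver and neural (0.94, 0.50), 4 of 8 mesenchymal (0.58, 0.43), 2 of 3 other epithelial (0.43, 0.45), 3 of 5 miR-34 and miR-449 (0.25, 0.56) and 3 of 5 inflammation-responsive members (1.88, 0.56) lay higher. The miR-17/92 clusters had 9 of 17 members higher, with a median of 0.34 and a mean of −0.14 (adjusted p = 0.45). The muscle and liver and neural lists pointed down without the second knockdown library, but the 3NC libraries differed too. Summed muscle miRNAs had 418 and 21324 CPM with knockdown against 225 and 3297 CPM in 3NC. Summed liver and neural miRNAs had 1455 and 11135 CPM against 785 and 3292 CPM. Each knockdown library thus lay above the 3NC library of the same number, although the labels do not pair them. Lower were 5 of 6 miR-29 members (−1.14, 0.41) and 24 of 35 lactation and milk fat members (−0.63, 0.27), such as miR-23a at 6090 ± 2181 against 13683 ± 722 CPM and miR-24-3p at 6233 ± 4797 against 11663 ± 4458 CPM. The sign of the median turned under another scaling for each of these lists except the inflammation-responsive one (0.15 to 3.46). MiR-21-5p of that list had 110025 CPM in the first knockdown library and 4548 CPM in the second.

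The controls were compared as background. MiR-183 stood at 65.6 ± 34.8 CPM in 3NC against 5803 ± 7160 CPM in 5NC (log2 fold change −6.47 ± 1.60 SE), novel_mir5 at 75.3 ± 23.3 against 4502 ± 5689 CPM (−5.90 ± 1.71), and novel_mir399 at 0 reads against 280 ± 137 CPM. Without the first 5NC library the fold changes of miR-183 and novel_mir5 were −3.49 ± 1.10 and −2.67 ± 1.22. Liver miR-122 stood at 1316 ± 1726 against 22.7 ± 2.59 CPM (5.85 ± 2.19, but 2.07 ± 1.90 without the second 3NC library), and novel_mir261 and novel_mir137 at 17.96 ± 0.106 and 12.8 ± 1.47 CPM against 0 reads. By edgeR 0 of 402 miRNAs passed (smallest adjusted p = 0.67), 27 had an unadjusted p under 0.05 (8 higher, 19 lower), and DESeq2 called 16 (1 higher, 15 lower, 140 without an adjusted p). In 3NC against 5NC camera called the other epithelial (median −5.27), mesenchymal (1.97), miR-17/92 (−1.05) and miR-30 lists (−1.54), each at adjusted p = 0.0079 and at 0.61, 0.86, 0.61 and 0.44 with an estimated correlation. Overexpression against 5NC and 3NC against 5NC share the 5NC libraries, and edgeR called 20 miRNAs between the controls without the second 5NC library.

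The comparisons were then set against each other, to find miRNAs that differ in opposite directions after overexpression and knockdown. MiR-497-5p had 4.04 ± 3.46 CPM with overexpression against 532 ± 728 CPM in 5NC, and 66.9 ± 45.8 CPM with knockdown against 1.86 ± 1.81 CPM in 3NC. Its 5NC level rested on the first 5NC library (1047 CPM, against 17.3 CPM in the second). MiR-218 had 61.7 ± 14.0 against 601 ± 293 CPM and 276.9 ± 182.6 against 41.1 ± 3.84 CPM. For both, the mean with overexpression lay above that of 3NC, so the opposite signs depend on 5NC as the control. The 3NC level of miR-497-5p (3.14 and 0.58 CPM) lay near the floors of those libraries (2.35 and 1.73 CPM). These 2 were the only miRNAs with opposite signs and an unadjusted p under 0.05 in both comparisons, where chance gives 1.68, and 2 more had the same sign, where chance gives 1.94. DESeq2 called both miR-497-5p (adjusted p = 0.0061 and 0.0499) and miR-218 (0.029 and 0.045) in opposite directions, whereas edgeR called 0. DESeq2 also called 3 miRNAs higher in both, miR-126-3p (0.034 and 0.033), novel_mir734 and novel_mir640. The last 2 had reads in only 1 library of each treated group, novel_mir734 at 32.4 CPM with overexpression and 578 CPM with knockdown, and novel_mir640 at 9.55 and 365 CPM. Fold changes of the comparisons, which share no library, correlated across the 402 miRNAs at a Pearson r of −0.16 and a Spearman rho of −0.15, and at −0.08 and −0.05 across the 269 known ones. Signs matched for 161 miRNAs (40.05%).

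In the test of the difference between the effects, miR-497-5p (difference −12.30 ± 3.21 SE on the log2 scale) and miR-218 (−6.03 ± 1.65) had the lowest p on the lower side with novel_mir9. Without the first 5NC library the difference was −7.36 ± 2.43 for miR-497-5p and −5.41 ± 1.49 for miR-218 (edgeR adjusted p = 0.35 for both). On the higher side stood let-7b-3p (5.04 ± 1.45), miR-767 and novel_mir261, the last 2 with 0 reads in both knockdown libraries and at most 8.65 and 18.04 CPM in 3NC. By edgeR 0 miRNAs passed (smallest adjusted p = 0.36), 48 had an unadjusted p under 0.05 (25 higher, 23 lower), and DESeq2 called 13 (4 higher, 9 lower, 86 without an adjusted p). Camera called the other epithelial (median −5.86, adjusted p = 0.011), miR-17/92 (−1.61, 0.011) and miR-30 lists (−2.25, 0.0049) lower in the overexpression effect, at adjusted p = 0.67, 0.67 and 0.32 with an estimated correlation. Under the other scalings these medians ran from −7.36 to −4.66, from −3.30 to −0.53 and from −3.38 to −1.49. Without the second 5NC library edgeR called 42 miRNAs in this test.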

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

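All tests in this part except the depth test of the first 5NC library were chosen after the values were seen, as was the rule for picking out small RNA classes: at least 1% of the reads of a library and more than 2 times the highest control library.

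The first 5NC library stood apart from the other controls, with miR-204-5p at 17.3 CPM against 59785 to 192258 CPM, miR-3432-5p at 3.87 CPM against 10159 to 13096 CPM and miR-497-5p at 1047 CPM against 0.58 to 17.3 CPM. After thinning to equal depth its Spearman correlation with the second 5NC library was 0.632, against at least 0.777 among the other controls, which argues against depth, and its highest correlation with a library of another group was 0.635, below the 0.759 of the least alike pair within the other groups, which argues against a swap with one of them. The second 5NC library had the same treatment, so the 5NC treatment alone does not account for the gap either. Reads of another species stay open as a candidate explanation. A set of 10 miRNAs with numbers first given to ruminants had 1 read in it and 14, 26 and 35 in the other controls. Its rate was 0.0246 times the lowest of the other controls (exact 95% interval 0.000581 to 0.162). This rate cannot decide the question, because miRNAs outside the set, which left out miR-3432-5p, were nearly absent too. MiR-197-3p had 0.26 CPM there against 992 to 1845 CPM in the other controls, and miR-28-3p 0 against 296 to 401 CPM. Others were higher there, such as miR-497-5p and miR-183. A different mix of cells was not excluded, although the miR-200 family lay between −2.72 and 1.24 log2 units from the other controls while miR-96, miR-182 and miR-183 lay 3.24 to 6.26 units above them.

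Endothelial miR-126-3p stood at 6417 to 10214 CPM in both knockdown libraries and the second overexpression library, and at 207 to 699 CPM in the other 5. Per 1000000 reads of the whole library, the first knockdown (477.1) and second overexpression libraries (430.9) stood at no less than 4.24 times the highest of the others (101.7), which argues there against a fixed share of outside RNA in every library, and against carry-over of reads from the others, as the whole cause. The second overexpression library stood at 4.30 times the highest control. The labels give it no knockdown, so its level is no test of knockdown as a cause. It shows only that a high level occurred without that label, and an effect in the knockdown libraries stays open. For the second knockdown library (101.4) the ratio to the highest of the others was 0.997, or 1.78 with predicted piRNAs left out of the totals. The repeat class, which may hold the same piRNA reads again, stayed in these totals. If it does, 1.78 is too low, so a fixed share could not be settled there. A fixed amount of outside RNA beside a low yield was not tested, since RNA yield was not analysed here.

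Predicted piRNAs took 43.9% of the reads of the second knockdown library, against at most 0.303% in a control, and novel_pir1385, placed in a LINE/L1 repeat by its identifier, took 39.2% with 12558904 reads against 0 in the other 7 libraries. The repeat class took 40.4% there against at most 16.4% in a control. The first knockdown library, given the same treatment, had 0 reads of novel_pir1385, which allows a share of up to 4.55e-05% and argues against the knockdown reagent as its source. The excess of the repeat class over the other libraries came to 0.874 times the predicted piRNA reads, so the same reads may have been counted in both. Where these reads came from stays open.

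Other classes stood out by the same rule. In the second overexpression library the Rfam families outside the named classes took 39.7% of reads (at most 17.9% in a control), of which transfer-messenger RNA, a bacterial family, took 39.2% (at most 16.6%). The second knockdown library also held 4.19% of novel_pir2713, placed in a LINE/L2 repeat, against 0 reads in the controls. In the first knockdown library ribosomal RNA took 27.3%, tRNA 2.568% with its Rfam family at 2.567%, and snoRNA 1.43%, against at most 4.89%, 0.728%, 0.728% and 0.378% in a control. Its ribosomal families were the eukaryotic small subunit (8.21%, at most 1.03% in a control), the bacterial large subunit (7.11%, 0.819%), the bacterial small subunit (4.97%, 0.471%) and the eukaryotic large subunit (2.78%, 0.489%). These families match across kingdoms, so a bacterial family name does not place a read in bacteria.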

How the results depend on the processing

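Scaling to miRNA totals, mature features alone, thinning, leaving out the doubted libraries together and the list tests with libraries left out, thinned or scaled to totals were chosen after the data were seen. The 0 calls of edgeR stayed 0 in all 4 comparisons with DESeq2 size factors, known miRNAs alone, mature and hairpin features apart, mature features alone, miRNA totals, thinning, and neither the first 5NC nor the second overexpression library, for the main comparisons and the controls with only the groups compared, and for both main comparisons with the other control or all 4 controls. DESeq2 called 26 for overexpression, 25 for knockdown, 16 between the controls, 13 in the difference of effects and 2 in opposite directions. Without a low-count filter edgeR called 5, 5, 2 and 5 in that order, with a mean of at least 10 CPM 6, 8, 7 and 4, and with totals of all named small RNAs 1 for overexpression and 3 for the difference. The cause was not tested. Leaving out 1 library gave 0 to 30 calls for overexpression, 0 to 0 for knockdown, 0 to 20 between the controls and 0 to 42 for the difference, with the counts of 30, 20 and 42 reached without the second 5NC library. The lone library left in a group was then assumed to vary like the other groups.

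The 9 list calls of the main comparisons became 0 with an estimated correlation, 0 with fry, 2 with totals of all named small RNAs, 3 after thinning, 6 without the doubted libraries, 9 with DESeq2 size factors and 2 to 10 when 1 library was left out, fewest without the second 3NC library. Across single results the alternatives kept the side of the threshold in 454 cases, put 40 past it, took 57 back and moved 26 values, with 0 reversed. These cases cover named miRNAs and called lists by the direction of the test, not the list medians whose sign turned with scaling or the lists not called. Novel_mir160 has no value against 3NC, where both groups were at 0.

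With the replicate number as a block, edgeR called 0 miRNAs in each comparison. The paired list tests gave 9 calls, with the muscle list called for overexpression (adjusted p = 0.027) and knockdown (0.031) and the mesenchymal (0.073) and miR-221 (0.089) calls lost. Deviations of libraries with the same number correlated at −0.067 for 5NC and overexpression, 0.148 for 3NC and knockdown, −0.035 for 3NC and 5NC, 0.151 for 3NC and overexpression, 0.056 for 5NC and knockdown and 0.297 for overexpression and knockdown. With 2 numbers, no batch in the labels and 3 of 6 values under 0.1, the numbers were not taken as pairs. All 3 of these low values involve 5NC, whose first library stood apart, so an effect shared by libraries of one number was not excluded. Other pseudocounts were not run because the tests used counts. Depth limited the knockdown group most, where 3 reads equal 8.76 and 9.43 CPM.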

Other observations

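The tests of hairpin arms in this part were planned, and the libraries compared in the next paragraph were chosen after their values were seen.

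The summed muscle miRNAs stood at 3297 CPM (3NC), 1355 CPM (5NC), 3724 CPM (overexpression) and 21324 CPM (knockdown) in the libraries numbered 2, and at 225, 171, 229 and 418 CPM in those numbered 1. MiR-206, made in skeletal muscle, had 1328, 1634 and 9513 CPM in the second 3NC, overexpression and knockdown libraries and 3.14, 21.3 and 8.76 CPM in the first, whereas in 5NC the order was opposite, with 163 CPM in the first and 17.3 CPM in the second. Muscle miR-133a-3p had 1274, 1021, 1381 and 7335 CPM in the second libraries and 125.5, 4.38, 73.2 and 254 CPM in the first. Liver miR-122 had 2537, 2371 and 9636 CPM in the second 3NC, overexpression and knockdown libraries against 95.7, 116.8 and 1291 CPM in the first, and 24.5 and 20.9 CPM in 5NC. Labels give no batch for these numbers.

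Levels of miR-21-5p, among the most abundant miRNAs of cultured cells, also parted within groups, with 202474 and 9775 CPM in the overexpression libraries and 110025 and 4548 CPM in the knockdown libraries, against 116739 and 112978 CPM in 3NC.

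One hypothesis was that both arms of a hairpin change together, as they are made from one precursor. Across the 71 hairpins with both arms measured, which are not independent replicates, the fold changes of the arms correlated at a Pearson r of 0.255 for overexpression against 5NC (one-sided permutation p = 0.0169) and 0.386 for knockdown against 3NC (p = 0.0008), with the same sign for 46 of 71 hairpins in each. Differences between libraries that reach the precursor could give this, whether they come from the treatment, the cells or the library, and the correlation does not separate these. Each arm was the sum of its mature and hairpin features. If reads of one precursor are counted in the hairpin features of both arms, which is not given, the arms would correlate through the counting alone. The test was not run on mature features alone, so it cannot decide the hypothesis.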
